A study of Mus musculus with 32 samples.

How the data were processed

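Gene expression was measured by RNA sequencing of polyA RNA from whole liver of male C57BL/6 mice aged 16 weeks. Per the labels, 4 animals were taken for each of 8 groups that crossed genotype (wild type, WT, or disrupted for the fatty acid transport protein Fatp2, KO), diet (a ketogenic diet, KD, or its control diet, CD, fed from 12 weeks of age) and hours of fasting before death (4 or 24). Each library is a separate animal, and replicate numbers follow the order of deposit only. The numbers in the sample titles form separate ranges for WT and KO, and within each genotype for 4 and 24 h of fasting. Their meaning is not given, so a batch or order of collection tied to them cannot be told apart from genotype or fasting time. Libraries were made with an Illumina TruSeq RNA kit and sequenced from both ends, per the labels' protocols. The strand setting of the counting and the annotation release are not given in the sources used here, so genes that overlap on opposite strands cannot be separated.

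The deposited table holds read counts per gene and FPKM values for 35275 genes in 32 libraries. Reads were aligned with Bowtie2 2.2.3 and TopHat2 2.0.12 and counted with HTSeq 0.6.1 against mouse build GRCm38 (mm10), per the submitters' processing notes. The deposited FPKM values equalled the count divided by gene length and total count in 100% of comparisons, within 0.1%, and were not used further. All values below come from the deposited counts. Of the genes, 10278 had no read in any library. A spreadsheet had turned 27 gene symbols into dates, and these were restored through their gene identifiers. Another 122 duplicated symbols were made unique, and 34490 identifiers matched the GENCODE M21 name table. Coordinates are those of the deposited table.

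Total counts ranged from 13406678 to 24700310 per library, and 17334 to 19793 genes had at least 1 read. A gene with 3 counts in a library is at 0.121 to 0.224 CPM, the count scaled to normalised library size, and counting intervals and this floor cover counting error only. The 48 pairs of replicates had correlations of log counts between 0.9759 and 0.9975, and a chi-square per degree of freedom from 8.09 to 259.82, so no pair agreed within sampling noise.

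Counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr, R 4.3.3) in a model with a mean for each of the 8 groups, in which all 32 libraries shared the estimate of spread. After the filter 14438 genes were tested, with a common biological coefficient of variation of 0.235, 24 residual degrees of freedom and a median of 4.95 prior degrees of freedom. There were 12 pairwise contrasts (4 each of genotype, diet and fasting) and 7 interactions. Adjusted p values are Benjamini-Hochberg values from edgeR within a contrast, all tests were two-sided, and genes passed at an adjusted p under 0.05. Log2 fold changes carry a standard error (SE) taken as the fold change divided by the square root of the test's F statistic, so it restates the test. Levels are normalised CPM as mean ± SD of 4 animals. Genes that share reads with near-identical copies, such as Saa1 and Saa2, the Cyp4a family, Mup and Serpina pseudogenes, Hspa1b and Eif3j1 with Eif3j2, have uncertain counts.

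The 36 gene lists (512 symbols) were written before the data were examined, as were the groups, the design, the first set of alternatives and the rule for named genes. They cover liver metabolism, stress and immune responses, sex-biased genes and markers of other cell types. Each list was tested in each pairwise contrast with camera (limma 3.58.1), with a preset correlation of 0.01 between genes and adjustment over all 432 tests. Camera was repeated with a correlation estimated for each list. The rotation test fry asked whether a list's genes moved on balance in 1 direction, and its mixed form whether they changed in either direction. With the preset correlation 124 tests were called, of which 1 held with an estimated correlation, the PPARα targets in KO against WT on CD at 4 h. Fry called 84 tests for a direction and 128 for change in either direction.

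The genes named are Slc27a2 (the gene of Fatp2), members of the lists (up to 4 with the largest change in a contrast), and for each contrast the 3 with the highest and the 3 with the lowest log2 fold change. The last needed a mean of at least 5 CPM in a group and no overlap of the 4 libraries of each group. Up to 8 genes per direction were named among those that met this in all 4 contrasts of a factor, and 3 per direction by p for each interaction. Gene models without an official name were skipped, and some genes that met these rules are not reported here. Overlaps of calls were tested with Fisher's exact test (12 tests) between contrasts that share no library. Correlations across genes (4) were also taken only between contrasts that share no library. For overlaps and correlations alike, genes are not independent replicates, and all contrasts come from the same fit with a shared estimate of spread.

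Alternatives fixed at that time were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit of only the groups in a contrast, each replicate left out in turn, and genes of at least 5 CPM or an adjusted p under 0.01 for correlations and overlaps. Another 4 were chosen after seeing the data. They left out the 2 libraries near the other diet, 4 libraries that stood apart, 4 libraries with skeletal muscle transcripts, or 3 libraries low in Yam1 reads. Other splits of the same libraries were refitted with only the groups of the contrast, all 35 for a pairwise contrast and 100 drawn with a fixed seed for an interaction.

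The steps were tested on simulated counts with 200 changed genes among 14197. In a simulation of KO against WT on CD at 4 h, edgeR recovered 32% of genes changed by a factor of 1.5, 76% of those changed by 2, 94% of those changed by 4 and 94% of those changed by 0.25, with 8 false calls among 156. For the interaction of genotype and fasting on CD the shares were 0%, 42%, 76% and 82%, with 4 false calls among 104. DESeq2 made 22 and 13 false calls in these simulations, and 5 in a comparison with no change planted. A 1.5-fold change planted in the list of PPARα targets gave a camera p of 5.07e-17. The simulated genes varied independently of each other and no library stood apart. The simulations therefore do not show how the tests behave with correlated genes or such libraries. Summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.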

Results

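Transcript levels were measured in the livers of 32 male mice, 4 in each of 8 groups. WT mice and mice lacking Fatp2, a protein that carries long-chain fatty acids into cells and activates very long-chain ones, ate CD or KD and were fasted for 4 or 24 h. Ketogenic feeding and fasting are both states in which the liver burns fat and makes ketone bodies. Total counts ranged from 13406678 (WT KD 24 h replicate 2) to 24700310 (KO CD 4 h replicate 3). On the 2000 most variable genes the first principal component held 22.6% of the variance, the second 14.1% and the third 11.7%.

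Slc27a2, the gene that encodes Fatp2 (ENSMUSG00000027359; chromosome 2, 126552407 to 126588243, plus strand, GRCm38), was examined in every library. In WT livers it averaged 955 ± 41.1 CPM on CD at 4 h, 1870 ± 552 on CD at 24 h, 1100 ± 105 on KD at 4 h and 1310 ± 208 on KD at 24 h (SD, n = 4 each). In KO livers the means were 183 ± 41 on CD at 4 h, 295 ± 15.4 on CD at 24 h, 265 ± 46.1 on KD at 4 h and 263 ± 18 on KD at 24 h. The highest KO library (318 CPM) lay below the lowest WT library (905 CPM), so the genotype labels matched the gene's level in all 32 libraries. Log2 fold changes of KO against WT were −2.39 ± 0.19 (edgeR adjusted p = 2.78e-09) and −2.67 ± 0.20 (5.76e-10) on CD at 4 and 24 h, and −2.06 ± 0.19 (8.78e-08) and −2.32 ± 0.19 (6.42e-09) on KD.

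**Figure D1:**
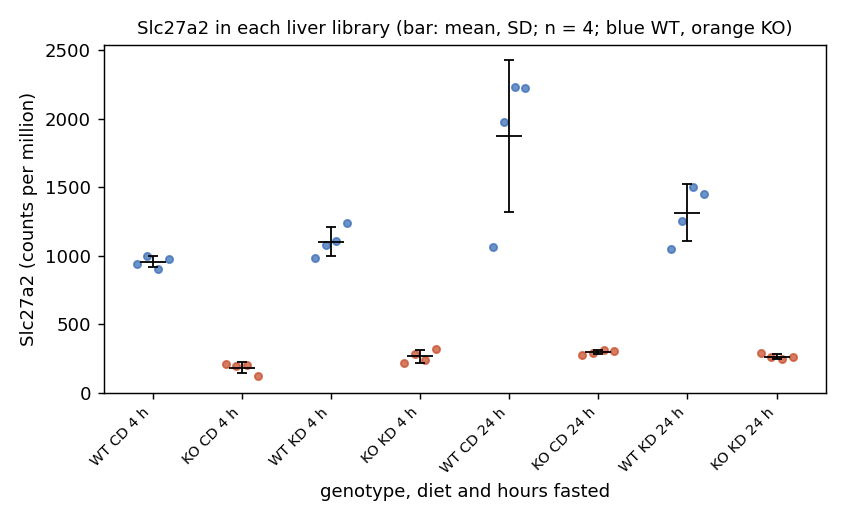
Slc27a2 level (CPM, vertical axis) in each of the 32 libraries by group (horizontal axis), points being single animals and lines the group mean with its SD. The KO libraries reach at most 318 CPM and the WT libraries start at 905 CPM.

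Several libraries stood apart from their groups, and their values are given here because they bear on the comparisons. Skeletal muscle transcripts were present in 4 livers: Acta1, skeletal muscle actin, was at 86.1 CPM in WT CD 24 h replicate 1, 78.4 and 178 CPM in KO CD 24 h replicates 1 and 2, and 162 CPM in KO KD 4 h replicate 4, against at most 0.504 CPM in the other 28. WT CD 24 h replicate 1 also had the lowest mean of the male-biased liver genes, 5.68 log2 CPM against 8.65 to 8.97 in its group. A diet position was computed from the 68 genes that KD changed in the same direction in WT livers at both times, with 0 at the WT CD mean and 1 at the WT KD mean. The library labelled KO CD 24 h replicate 4 lay at 0.98, against 0.29 to 0.47 for the other 3 of its group, and the library labelled KO KD 24 h replicate 4 at 0.44, against 0.96 to 1.01. The noncoding RNA Yam1 took 0.058% of counts in WT CD 4 h replicate 4, 0.06% in WT KD 24 h replicate 2 and 0.04% in KO CD 24 h replicate 1.

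**Figure D2:**
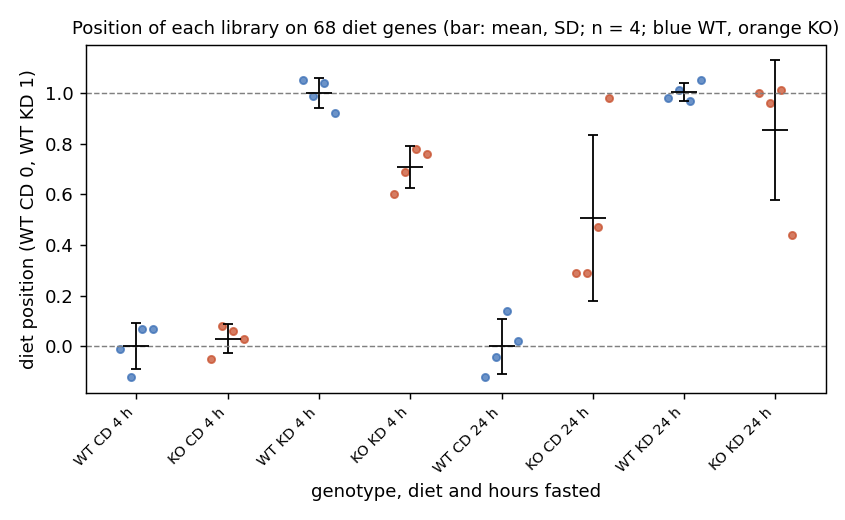
Diet position of each library over 68 genes (vertical axis, no unit; 0 is the WT CD mean and 1 the WT KD mean at the same hours) by group (horizontal axis), points being single animals and lines the group mean with its SD. The library labelled KO CD 24 h replicate 4 lies at 0.98 and the library labelled KO KD 24 h replicate 4 at 0.44.

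The number of genes that passed differed widely between the 12 contrasts. Between KO and WT livers 264 to 571 genes differed depending on condition, and between the longer and the shorter fast 1355 to 2703. Between the diets 3944 genes differed in WT livers at 4 h. In KO livers at 24 h 1 gene did by edgeR, with 1766 at an unadjusted p under 0.05 and 113 by DESeq2. A batch tied to the numbers in the sample titles cannot be told apart from genotype or fasting time.

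**Figure D3:**
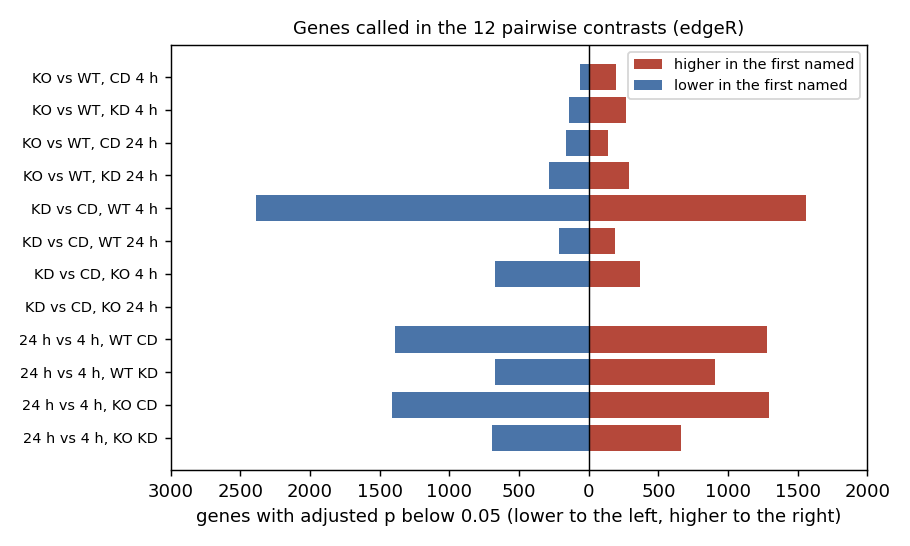
Number of genes past an adjusted p of 0.05 (edgeR) in each of the 12 pairwise contrasts, with genes higher and genes lower in the first-named group drawn as separate bars from 0. The counts run from 1 (KD against CD in KO livers at 24 h) to 3944 (KD against CD in WT livers at 4 h).

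KO and WT livers on CD after 4 h of fasting were compared to ask what loss of Fatp2 did on the control diet after a short fast. Genes of fatty acid oxidation were higher in KO livers. Cyp4a14, a microsomal fatty acid omega-hydroxylase, averaged 2750 ± 934 CPM in KO and 30.0 ± 23.5 in WT (SD, n = 4 each), a log2 fold change of 6.52 ± 0.53 (edgeR adjusted p = 2.78e-09). Of the 25 targets of PPARα, the nuclear receptor that induces fatty acid oxidation, 15 were higher and the other 10 did not pass (19 higher when adjusted over the list alone). Their median log2 fold change was 1.39, and the list was called higher (adjusted p = 0.00881 with an estimated correlation). Examples were Cyp4a10 (4.03 ± 0.62), Cyp4a31 (3.62 ± 0.55) and the pantetheinase Vnn1 (3.21 ± 0.37).

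Members of 4 further lists of lipid genes were examined on CD at 4 h. In peroxisomal β-oxidation 11 of 17 genes were higher (14 adjusted over the list alone; adjusted p = 0.0513 with an estimated correlation), among them the bifunctional enzyme Ehhadh, with a log2 fold change of 2.36 ± 0.36, and the very long-chain acyl-CoA transporter Abcd2 (1.68 ± 0.35). In mitochondrial β-oxidation 7 of 17 were higher (11 over the list alone; adjusted p = 0.0811 with an estimated correlation), such as Acadm (0.79 ± 0.15) and Eci2. Of 16 lipid droplet genes 5 were higher (9 adjusted over the list alone; adjusted p = 0.0811 with an estimated correlation). The droplet protein Cidea averaged 13.3 CPM in KO livers and 0.0417 CPM in WT, where its 4 libraries were at or below the floor of 3 counts (edgeR adjusted p = 3.92e-06), and the acyltransferase Mogat1 was higher by 5.19 ± 0.49. Of 16 genes of fatty acid uptake 2 were higher (4 higher and 1 lower over the list alone; adjusted p = 0.0811 with an estimated correlation), the scavenger receptor Cd36 (2.70 ± 0.31) and the transporter Slc27a1 (2.44 ± 0.30). Outside these groups, Vldlr was higher by 2.30 ± 0.49 and the female-biased cytochrome Cyp2b9 by 5.46 ± 1.15, while Moxd1 had a log2 fold change of −5.10 ± 1.04 and Lrtm1 of −3.52 ± 0.54. In all 264 genes passed, 199 higher and 65 lower (edgeR). The count was 166 without WT CD 4 h replicate 3 and 552 when only these 8 libraries were fitted.

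**Figure D4:**
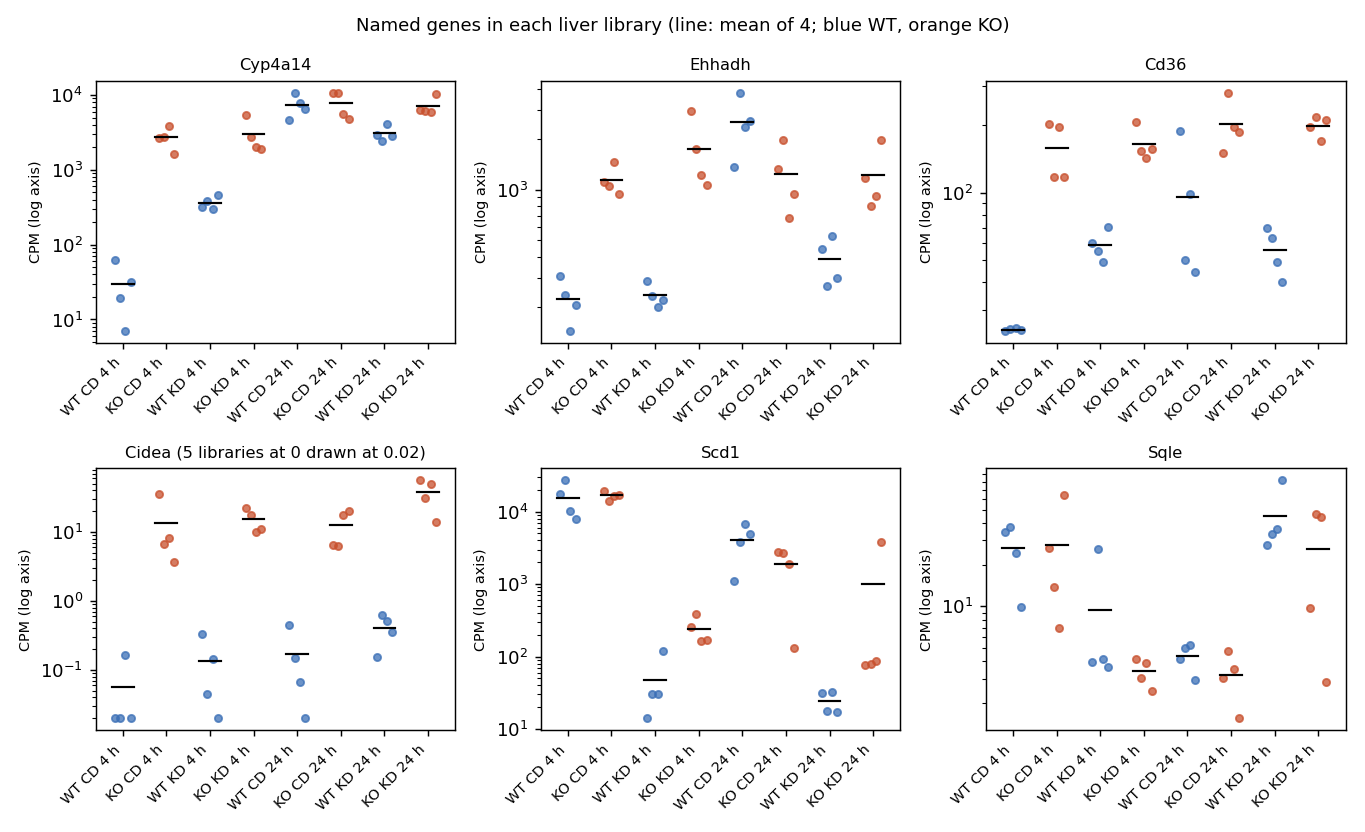
Levels (CPM, log vertical axes) of Cyp4a14, Ehhadh, Cd36, Cidea, Scd1 and Sqle in the 32 libraries by group (horizontal axis), points being single animals and lines group means, with libraries at 0 drawn at 0.02. Mean Cyp4a14 was 30.0 CPM in WT CD 4 h livers and 2750 CPM in KO CD 4 h livers, against 7370 and 7880 CPM at 24 h.

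The same genotypes were compared on KD at 4 h. The oxidation gene Ehhadh was again higher in KO livers: it averaged 1740 CPM in KO and 235 CPM in WT, a log2 fold change of 2.89 ± 0.37 (edgeR adjusted p = 1.69e-05, n = 4 each). PPARα targets were higher for 14 of 25 genes (18 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), with Cyp4a31 at 3.75 and Cyp4a14 at 3.05 ± 0.45. Peroxisomal genes were higher for 8 of 17 (14 over the list alone; adjusted p = 0.105 with an estimated correlation), such as the carnitine acyltransferase Crat (1.95). Mitochondrial genes were higher for 8 of 17 (13 over the list alone; adjusted p = 0.162 with an estimated correlation), such as Acadm (0.86). Lipid droplet genes were higher for 4 of 16 (6 higher and 1 lower over the list alone; adjusted p = 0.477 with an estimated correlation), with Cidea at 6.90 ± 0.84 and Mogat1 at 3.03. Cd36 was higher by 1.5 ± 0.3 and the fatty acid elongase Elovl5 by 1.53.

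Members of other lists also differed between the genotypes on KD at 4 h. Interferon-stimulated genes were lower for 4 of 17 (8 over the list alone; adjusted p = 0.477 with an estimated correlation), with the guanylate binding protein Gbp3 at −1.5 ± 0.26. The clock gene Cry1 (−1.35), the acute phase gene Orm3 (−2.57 ± 0.49) and the desmosomal gene Dsg1c (−3.27 ± 0.40) were lower. Higher genes included the amino acid transporter Slc1a4 (2.08) and the Wnt target Axin2 (1.12), both markers of pericentral hepatocytes. Markers of Kupffer cells and macrophages had a median of −0.60 (adjusted p = 0.507 with an estimated correlation). Of 406 genes that passed, 265 were higher and 141 lower (edgeR; 651 by DESeq2). Counts fell to 210 without KO KD 4 h replicate 1, 220 without KO KD 4 h replicate 2 and 244 without WT KD 4 h replicate 3, and came to 863 without the 4 libraries holding muscle transcripts.

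The genotypes were also compared on CD after 24 h of fasting, to ask how the difference looked after a long fast. The droplet gene Cidea averaged 12.5 CPM in KO and 0.166 CPM in WT (log2 fold change 5.85 ± 0.79, edgeR adjusted p = 7.88e-05, n = 4 each), and Mogat1 was higher by 2.49 ± 0.40. Mean Cyp4a14 was 7880 ± 3150 CPM in KO and 7370 ± 2480 in WT, and the PPARα targets had a median log2 fold change of −0.27. Markers of Kupffer cells and macrophages were lower for 8 of 12 genes (11 over the list alone), with a median of −1.28 (adjusted p = 0.231 with an estimated correlation). C1qc, a complement subunit made by macrophages, had a log2 fold change of −1.33 ± 0.27 in the full fit and −0.84 without WT CD 24 h replicate 1. It was −0.59 and did not pass without the 4 libraries holding muscle transcripts. Srebf1, the regulator of lipogenesis, was higher (1.66 ± 0.35), and asparagine synthetase Asns (−2.84 ± 0.52) and apolipoprotein Apoa4 (−2.77) were lower. These last 3 did not pass when only the groups of the contrast were fitted. The heat shock gene Hspa1b, whose reads can be shared with its copy, had a log2 fold change of −3.37 ± 0.55.

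In this contrast 299 genes passed, 136 higher and 163 lower (edgeR). The count depended on which libraries entered: 13 with only these 8 libraries, 563 by DESeq2, 115 without the 2 libraries near the other diet and 2247 without the 4 libraries holding muscle transcripts, 3 of which belong to these groups. Without a single library it was 105 (KO CD 24 h replicate 4), 149 (KO CD 24 h replicate 3) or 509 (WT CD 24 h replicate 3). The 2247 rests on replicates 3 and 4 alone in KO CD 24 h, and replicate 4 is among the libraries near the other diet.

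The last comparison of genotypes was on KD after 24 h of fasting. Cd36 was higher in KO livers: it averaged 199 CPM in KO and 55.3 CPM in WT, a log2 fold change of 1.85 ± 0.30 (edgeR adjusted p = 0.000393, n = 4 each), and Cidea 37.4 and 0.412 CPM (6.47 ± 0.74, 2.72e-06). PPARα targets were higher for 9 of 25 genes (12 over the list alone; adjusted p = 0.34 with an estimated correlation), mitochondrial genes for 7 of 17 (9 over the list alone; adjusted p = 0.324 with an estimated correlation) and peroxisomal genes for 6 of 17 (11 over the list alone; adjusted p = 0.231 with an estimated correlation). The acyl-CoA thioesterases Acot2 (1.67) and Acot3 (3.09 ± 0.56), Ehhadh (1.66), Slc27a1 (2.09), Mogat1 (3.05) and Vldlr (2.12) were among them or beside them. Oxidative phosphorylation genes were higher for 2 of 24 (8 over the list alone), with a median of 0.40 (adjusted p = 0.231 with an estimated correlation). Mitochondrially encoded genes took 11.3 ± 1.42% of counts in KO and 7.44 ± 2.25% in WT livers.

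Members of the acute phase, macrophage and interferon lists were examined in KO livers on KD at 24 h. Acute phase genes were lower for 8 of 18 (17 adjusted over the list alone; adjusted p = 0.148 with an estimated correlation), led by serum amyloid Saa2 (−6.56 ± 0.99) and Saa1 (−5.50 ± 0.82), which share reads. Kupffer cell and macrophage markers were lower for 6 of 12 (10 over the list alone; adjusted p = 0.245 with an estimated correlation), such as Clec4f (−1.39 ± 0.22) and Csf1r (−1.30), and interferon-stimulated genes for 4 of 17 (6 over the list alone; adjusted p = 0.477 with an estimated correlation), such as Gbp3 (−1.25). Complement C6 (−1.63) was lower, and the glutathione transferases Gstt3 (1.93 ± 0.24) and Gsta2 (1.86) and Cyp2b9 (7.57 ± 1.28) were higher. The adipocyte marker Cfd was higher by 3.24, but not past the threshold when only these groups were fitted. In log2 CPM Cfd was at 3.65 to 3.95 in KO KD 24 h replicates 1 to 3 and −0.25 to 1 in WT KD 24 h. In the library labelled KO KD 24 h replicate 4 it was at −2.41, below all of these. Scd1, the fatty acid desaturase, was higher by 5.35 ± 1.08, but by 1.73 and not past the threshold without the library labelled KO KD 24 h replicate 4. It was at 3770 CPM in that library and 76.5 to 87.7 CPM in the other 3. In all 571 genes passed, 289 higher and 282 lower (edgeR; 892 by DESeq2, 373 without the filter). Leaving out WT KD 24 h replicate 1 gave 939, replicate 2 226 and replicate 3 346, and leaving out KO KD 24 h replicates 1, 2, 3 and 4 gave 266, 278, 359 and 361.

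Calls between the genotypes overlapped across the 4 conditions, which share no library. Of the 199 and 265 genes higher in KO on CD and KD at 4 h, 100 were shared, against 3.65 for independent lists (Fisher's exact test, adjusted p = 2.45e-124). Genes are not independent, and each gene's spread came from the same fit in every contrast. The numbers for independent lists and the p values here are therefore descriptive. Between CD and KD at 24 h, 54 lower genes were shared against 3.18. The lowest odds ratio, 7.87, was that of genes lower on KD at 4 h and on CD at 24 h, with 11 shared against 1.59 (Fisher's exact test, adjusted p = 5.63e-07). In all 4 contrasts 30 genes were higher and 5 lower. Among them, with log2 fold changes on CD at 4 h, were the transporters Slc35f2 (4.37 ± 0.29) and Slc39a5 (2.95), the sulfotransferase Gal3st1 (3.70), the disintegrin gene Adam11 (1.78), the ribonuclease Pnldc1 (2.33) and Eif3j2 (4.04), and on the lower side the sulfotransferase Sult5a1 (−1.82) and the interferon regulatory factor Irf5 (−1.58). Irf5 averaged 7.00 ± 1.78 CPM in KO and 21 ± 3.99 in WT on CD at 4 h, and 4.65 ± 2.12 and 12.0 ± 2.45 on KD at 24 h.

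KD was compared with CD in WT livers at 4 h to ask what the ketogenic diet did after a short fast. Genes of fat synthesis were lower on KD: Scd1 averaged 48.1 CPM on KD and 15700 CPM on CD, a log2 fold change of −8.35 ± 1.23 (edgeR adjusted p = 1.52e-05, n = 4 each), and fatty acid synthase Fasn 65.1 and 770 CPM (−3.56 ± 0.56). Of 19 lipogenesis genes 16 were lower and 3 did not pass (17 lower and 1 higher over the list alone; adjusted p = 0.211 with an estimated correlation), including Pnpla3 (−5.42) and Elovl5 (−3.33 ± 0.30). Of 25 cholesterol synthesis genes 16 were lower (16 over the list alone as well; adjusted p = 0.602 with an estimated correlation), such as Dhcr7 (−2.06 ± 0.38). WT KD 4 h replicate 2 had a mean of 5.89 log2 CPM over this list, against 4.46 to 4.53 in the other 3 libraries. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was higher by 3.77 ± 0.63, while 6 of the 17 bile acid genes were lower (7 lower and 1 higher over the list alone; adjusted p = 0.825 with an estimated correlation), among them the export pump Abcb11 (−1.93 ± 0.21).

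Clock genes changed in both directions in WT livers on KD at 4 h. Of 17, 9 were higher and 4 lower (9 and 4 over the list alone as well; adjusted p = 0.231 with an estimated correlation): Ciart (5.23 ± 0.77) and Usp2 (4.50 ± 0.51) were higher, and the activators Arntl (−3.82 ± 0.42) and Npas2 (−5.49 ± 0.79) lower. Arntl averaged 1.33 ± 0.701 CPM on KD and 18.7 ± 8.41 on CD. Whether the groups were collected at the same time of day was not examined, for this or any other contrast. PPARα targets included both Cyp4a14 (3.61 ± 0.47) and Acot1 (1.84 ± 0.38), which were higher, and Plin2 (−1.83 ± 0.30) and the hormone gene Fgf21 (−2.46 ± 0.51), which were lower. Genes of the ER unfolded protein response were lower for 10 of 15 and higher for 1 (10 and 1 over the list alone; adjusted p = 0.687 with an estimated correlation), with Pdia4 at −1.68 and Hyou1 at −1.60. Atf5, a stress-induced transcription factor, fell by 2.50 on the log2 scale (SE 0.22, edgeR adjusted p = 1e-08).

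Members of the acute phase, amino acid and periportal lists were examined on KD in WT livers at 4 h. Acute phase genes were lower for 12 of 18 and higher for 1 (12 and 1 over the list alone; adjusted p = 0.623 with an estimated correlation), with the fibrinogen genes Fga (−2.05), Fgb (−1.64) and Fgg (−1.63) lower and Orm3 (3.16) higher. Amino acid catabolism genes were lower for 9 of 20 (10 over the list alone; adjusted p = 0.722 with an estimated correlation), such as Hal (−1.51) and Cps1 (−1.27). Periportal markers were lower for 7 of 12 (7 lower and 1 higher over the list alone; adjusted p = 0.539 with an estimated correlation), with Cdh1 at −2.13. The male-biased elongase Elovl3 (−3.75), the receptor gene Chrna4 (−6.44) and the glutathione transferase Gstm3 (−2.02) were lower, and the P450 reductase Por (2.39) was higher. Cfd, the only tested gene of the adipocyte marker list, was higher by 4.40, at 0.46 to 12 CPM on KD and 0.0633 to 0.362 CPM on CD. Mitochondrial transcripts took 11.7 ± 2.82% of counts on KD and 6.01 ± 0.402% on CD. In all 3944 genes passed, 1557 higher and 2387 lower (edgeR), and 2541 passed without WT KD 4 h replicate 1.

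At 24 h of fasting the diets were compared again in WT livers. The oxidation gene Ehhadh was lower on KD: it averaged 385 CPM on KD and 2520 CPM on CD, a log2 fold change of −2.71 ± 0.36 (edgeR adjusted p = 0.000254, n = 4 each). PPARα targets were lower for 13 of 25 genes (22 over the list alone; adjusted p = 0.105 with an estimated correlation), such as Acot1 (−2.29). Peroxisomal genes were lower for 8 of 17 (10 over the list alone; adjusted p = 0.119 with an estimated correlation), such as Acot3 (−3.06) and Crat (−1.23), and mitochondrial genes for 5 of 17 (12 over the list alone; adjusted p = 0.231 with an estimated correlation). Lipid droplet genes were lower for 5 of 16 (9 over the list alone; adjusted p = 0.37 with an estimated correlation), such as Fitm2 (−1.11). Cholesterol synthesis genes were higher for 14 of 25 (21 over the list alone; adjusted p = 0.229 with an estimated correlation), with Idi1 at 3.75 ± 0.71, Msmo1 at 3.42 ± 0.58 and Sqle at 3.36 ± 0.74. WT KD 24 h replicate 4 had the highest mean of this list, 6.63 log2 CPM against 5.75 to 5.87.

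Lipogenic genes went in different directions in WT livers at 24 h. Scd1 was lower on KD (−7.38 ± 1.19) and Elovl5 lower (−1.32), while Srebf1 was higher (2.11 ± 0.35). Genes of the unfolded protein response were higher for 3 of 15 (9 over the list alone; adjusted p = 0.333 with an estimated correlation), with Sdf2l1 at 2.62 ± 0.38, and acute phase genes for 4 of 18 (7 over the list alone; adjusted p = 0.432 with an estimated correlation). Stellate cell and fibroblast markers were lower for 4 of 12 (7 over the list alone), with a median of −0.99 (adjusted p = 0.231 with an estimated correlation). WT CD 24 h replicate 1, which held muscle transcripts, had the highest mean of this list, 4.88 log2 CPM against 3.63 to 4.18 in its group and 3.28 to 3.52 on KD. That library also had the lowest mean of the unfolded protein response list. It was 5.49 log2 CPM against 6.6 to 7.08 in its group and 7.15 to 7.61 on KD. Apoa4 averaged 160 ± 39.8 CPM on KD and 1640 ± 653 on CD (−3.36 ± 0.48). In all 401 genes passed, 190 higher and 211 lower (edgeR), with 700 by DESeq2, 46 when only these 8 libraries were fitted and 191 without the 3 libraries low in Yam1. The count was 187 without WT KD 24 h replicate 4, 231 without WT KD 24 h replicate 2, 262 without WT CD 24 h replicate 2 and 610 without WT CD 24 h replicate 3.

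KD was likewise compared with CD in KO livers at 4 h, and fat synthesis genes were lower on KD. Scd1 averaged 244 CPM on KD and 16700 CPM on CD, a log2 fold change of −6.10 ± 1.12 (edgeR adjusted p = 0.0013, n = 4 each), and Fasn 64.3 and 926 CPM (−3.85 ± 0.57). Lipogenesis genes were lower for 15 of 19 (16 over the list alone; adjusted p = 0.105 with an estimated correlation), such as Elovl6 (−2.82). Cholesterol synthesis genes were lower for 18 of 25 (23 over the list alone; adjusted p = 0.348 with an estimated correlation), such as Mvd (−3.49) and Fdps (−3.03). Gluconeogenesis genes were lower for 7 of 11 (8 over the list alone; adjusted p = 0.375 with an estimated correlation), such as Got1 (−2.16). Clock genes were higher for 6 of 17 and lower for 3 (8 and 3 over the list alone; adjusted p = 0.31 with an estimated correlation), with Per3 at 2.50, Arntl at −2.47 and Npas2 at −3.27. Cyp7a1 was higher by 4.44 ± 0.66. Mitochondrially encoded genes took 9.32 ± 3.4% of counts on KD and 5.44 ± 0.171% on CD.

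Some members of 3 other lists were lower on KD in KO livers at 4 h. Acute phase genes were lower for 8 of 18 (12 over the list alone; adjusted p = 0.37 with an estimated correlation), such as Fgb (−1.19). Unfolded protein response genes were lower for 8 of 15 (11 over the list alone; adjusted p = 0.554 with an estimated correlation), and periportal markers for 6 of 12 (8 over the list alone; adjusted p = 0.453 with an estimated correlation), such as Aldh1b1 (−2.01). Chrna4 (−7.68), Pnpla3 (−5.66) and Cyp17a1 (−3.09) were also lower. Of 1042 genes that passed, 369 were higher and 673 lower (edgeR). The count was 463 without KO KD 4 h replicate 4, which held muscle transcripts, 481 without KO KD 4 h replicate 3 and 1881 without KO KD 4 h replicate 1. Without KO CD 4 h replicate 1 it was 605, without replicate 2 668 and without replicate 4 596.

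In KO livers at 24 h few genes passed between the diets. The edgeR fit called 1 gene, the cholesterol synthesis enzyme Msmo1, higher on KD by 3.37 ± 0.58 (adjusted p = 0.0365, n = 4 each), while 1766 genes had an unadjusted p under 0.05 and DESeq2 called 113. Cholesterol synthesis genes had a median log2 fold change of 1.18, with 20 of 25 higher adjusted over the list alone (adjusted p = 0.282 with an estimated correlation). Mean Sqle was 25.8 CPM on KD and 3.22 CPM on CD. Without the 2 libraries that lay near the other diet 52 genes passed, and without the 4 libraries that stood apart 166. Leaving out the library labelled KO KD 24 h replicate 4 gave 26 and that labelled KO CD 24 h replicate 4 gave 7. The count was 0 without KO CD 24 h replicate 2 or 3 or without KO KD 24 h replicate 2 or 3 and in a fit of only these 8 libraries, and the Msmo1 call was lost under 8 of 16 alternatives, including the omission of KO CD 24 h replicate 1.

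Livers after 24 and 4 h of fasting were compared next, beginning with WT livers on CD. Oxidation genes were higher after the longer fast: Cyp4a14 averaged 7370 ± 2480 CPM at 24 h and 30.0 ± 23.5 at 4 h, a log2 fold change of 7.94 ± 0.57 (edgeR adjusted p = 2.89e-10, n = 4 each). PPARα targets were higher for 22 of 25 genes (23 over the list alone; adjusted p = 0.105 with an estimated correlation), such as Cyp4a10 (5.90) and Acot1 (4.55). Mitochondrial genes were higher for 13 of 17 (13 over the list alone; adjusted p = 0.211 with an estimated correlation), such as Acadm (1.42) and Hadhb (1.27), and peroxisomal genes for 13 of 17 (14 over the list alone; adjusted p = 0.199 with an estimated correlation), such as Ehhadh (3.50) and Crat (2.08). Ketogenesis genes were higher for 5 of 7 and lower for 1 (5 and 1 over the list alone; adjusted p = 0.492 with an estimated correlation). Lipid droplet genes were higher for 10 of 16 and lower for 1 (10 and 1 over the list alone; adjusted p = 0.231 with an estimated correlation), such as Cidec (4.59) and Plin5 (2.15).

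Synthesis genes were lower after the longer fast in WT livers on CD. Lipogenesis genes were lower for 16 of 19 (16 over the list alone; adjusted p = 0.174 with an estimated correlation), with Fasn at −4.25 ± 0.58 and Thrsp at −4.17. Cholesterol synthesis genes were lower for 20 of 25 (24 over the list alone; adjusted p = 0.419 with an estimated correlation), such as Fdps (−3.69) and Insig1 (−3.01). Genes of glucose use were lower for 9 of 13 and higher for 1 (10 and 1 over the list alone; adjusted p = 0.34 with an estimated correlation), among them pyruvate kinase Pklr (−3.86). Unfolded protein response genes were lower for 7 of 15 (9 over the list alone; adjusted p = 0.507 with an estimated correlation), with Sdf2l1 at −2.66. Cyp7a1 (2.71), Asns (3.42), the urea cycle gene Asl (1.70) and the steroid hydroxylase Cyp17a1 (4.01) were higher. After Cyp4a14, the highest fold changes by the naming rule were those of the estrogen sulfotransferase Sult1e1 (6.62) and of Gpnmb (6.46), a lysosomal glycoprotein of macrophages. WT CD 24 h replicate 1, with its muscle transcripts and low male-biased genes, is part of this contrast. In all 2670 genes passed, 1283 higher and 1387 lower (edgeR), and 1552 when only these 8 libraries were fitted.

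In WT livers on KD acute phase genes were higher after the longer fast. Of 18, 17 were higher and 1 did not pass (17 over the list alone as well; adjusted p = 0.105 with an estimated correlation), with Saa2 at 5.81, Saa1 at 4.68, the iron-binding gene Lcn2 at 3.98 and Orm2 at 2.82. Atf5 was higher by 2.88 ± 0.23 (edgeR adjusted p = 3.12e-09, n = 4 each). PPARα targets were higher for 6 of 25 and lower for 1 (9 and 2 over the list alone; adjusted p = 0.722 with an estimated correlation), with Cyp4a14 at 3.08 and Fgf21 at 2.76. Cholesterol synthesis genes were higher for 8 of 25 (12 over the list alone; adjusted p = 0.523 with an estimated correlation), such as Hmgcs1 (2.14). Amino acid genes were higher for 8 of 20 (10 over the list alone; adjusted p = 0.523 with an estimated correlation) and interferon-stimulated genes for 4 of 17 (10 over the list alone; adjusted p = 0.558 with an estimated correlation), such as Isg15 (1.57). Clock genes were lower for 6 of 17 and higher for 3 (6 and 4 over the list alone; adjusted p = 0.375 with an estimated correlation), with Per3 at −2.10, Arntl at 3.24 and Npas2 at 3.53. Unfolded protein response genes were higher for 6 of 15 (8 over the list alone; adjusted p = 0.658 with an estimated correlation). Sinusoidal endothelial markers were lower for 4 of 10 (5 over the list alone; adjusted p = 0.507 with an estimated correlation). Cyp17a1 (4.62), Moxd1 (4.15) and Asns (3.11) were higher, and the lipogenic gene Thrsp (−3.28) was lower. Mitochondrially encoded genes took 7.44 ± 2.25% of counts at 24 h and 11.7 ± 2.82% at 4 h. In all 1576 genes passed, 904 higher and 672 lower (edgeR). The count was 1002 without WT KD 24 h replicate 4 and 967 when only these 8 libraries were fitted.

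In KO livers on CD synthesis genes were lower after the longer fast, while the PPARα targets had a median log2 fold change of 0.11. Fasn averaged 40.3 CPM at 24 h and 926 CPM at 4 h, a log2 fold change of −4.52 (n = 4 each). Lipogenesis genes were lower for 17 of 19 (19 over the list alone; adjusted p = 0.107 with an estimated correlation), such as Acly (−2.76). Cholesterol synthesis genes were lower for 21 of 25 (23 over the list alone; adjusted p = 0.375 with an estimated correlation), such as Fdps (−3.87) and Sqle (−3.12), and glucose use genes for 9 of 13 (10 over the list alone; adjusted p = 0.375 with an estimated correlation), such as Pklr (−2.73). Among oxidation genes Acot3 (2.24) and Acot4 (1.11) were higher, and Acaa1b (−1.07) lower. Cyp7a1 was higher by 4.36. Cell cycle genes were lower for 7 of 16 (8 over the list alone; adjusted p = 0.554 with an estimated correlation), such as Top2a (−2.02) and Mcm5 (−1.60). Kupffer cell and macrophage markers were lower for 5 of 12 (5 over the list alone; adjusted p = 0.623 with an estimated correlation), such as Csf1r (−1.22). The 3 genes with the highest fold changes were the muscle transcripts Acta1, Tnnt3 and Tcap, which were high in KO CD 24 h replicates 1 and 2. Mitochondrially encoded genes took 11.1 ± 4% of counts at 24 h and 5.44 ± 0.171% at 4 h. In all 2703 genes passed, 1295 higher and 1408 lower (edgeR). The count was 1536 without KO CD 24 h replicate 3, 1791 without KO CD 4 h replicate 4 and 4259 without the 4 libraries holding muscle transcripts. The 4259 rests on replicates 3 and 4 alone in KO CD 24 h.

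In KO livers on KD genes of amino acid breakdown were higher after the longer fast. Of 20, 12 were higher and 8 did not pass (15 higher over the list alone; adjusted p = 0.282 with an estimated correlation), such as Got1 (2.22), the urea cycle genes Asl (1.82) and Ass1 (1.41), and arginase Arg1 (1.25). Cholesterol synthesis genes were higher for 10 of 25 (16 over the list alone; adjusted p = 0.623 with an estimated correlation), such as Mvd (3.09), Sqle (2.93) and Msmo1 (2.49), with Sqle at 25.8 CPM at 24 h and 3.39 CPM at 4 h. Interferon-stimulated genes were higher for 7 of 17 (7 over the list alone; adjusted p = 0.58 with an estimated correlation), such as Ifit1 (1.67), and targets of the xenobiotic receptors CAR and PXR for 4 of 17 (5 over the list alone; adjusted p = 0.332 with an estimated correlation), such as Cyp3a25 (1.66). Sinusoidal markers were lower for 4 of 10 (7 over the list alone; adjusted p = 0.477 with an estimated correlation). Cyp17a1 (4.00, and 2.62 without the 4 libraries that stood apart), Nnmt (3.34) and Atf5 (1.72) were higher, and the transcriptional repressor Bcl6 (−2.46) and the lipogenic regulator Mlxipl (−1.45) lower. In all 1355 genes passed, 659 higher and 696 lower (edgeR). Counts without a library were 747 (KO KD 24 h replicate 4), 752 (KO KD 4 h replicate 1), 793 (KO KD 24 h replicate 2), 820 (KO KD 4 h replicate 2) and 874 (KO KD 24 h replicate 1).

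**Figure D5:**
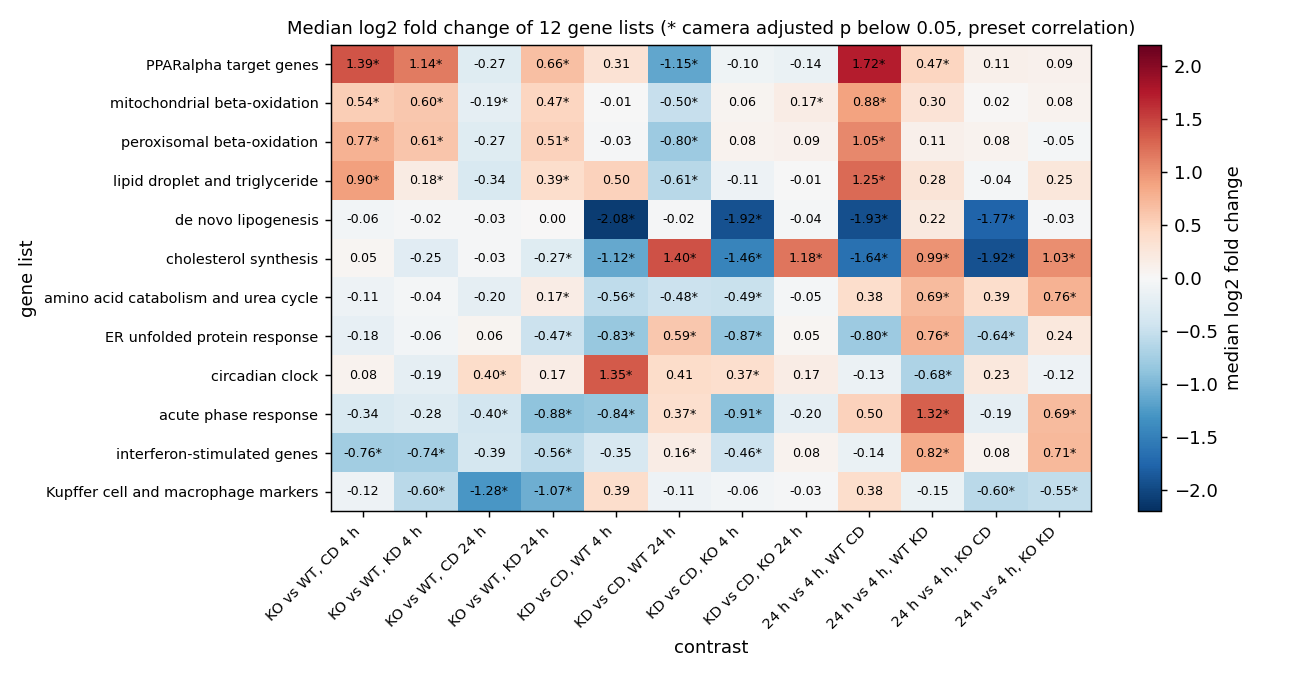
Median log2 fold change (colour) of 12 gene lists (vertical axis) in the 12 pairwise contrasts (horizontal axis), an asterisk marking an adjusted p under 0.05 in the list test with a preset correlation. The PPARα targets have medians of 1.39 in KO against WT on CD at 4 h and 1.72 for fasting in WT on CD.

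By the rule of no overlap between libraries, 33 genes were higher and 21 lower after the longer fast in all 4 combinations of genotype and diet. Betaine-homocysteine methyltransferase Bhmt, with log2 fold changes of 1.94 and 2.22 in WT and 1.69 and 2.53 in KO on CD and KD, and methionine adenosyltransferase Mat1a (2.26, 1.71, 1.65 and 1.97) belong to methionine metabolism. Mat1a averaged 10900 ± 2650 CPM in WT CD 24 h livers and 2280 ± 86.0 in WT CD 4 h livers. Cyp2c70, which makes muricholic acids in mice, had log2 fold changes of −3.88 and −1.86 in WT and −2.13 and −1.53 in KO on CD and KD. For diet the rule was met in all 4 contrasts by 0 genes, KO livers at 24 h having 1 call in edgeR and 113 by DESeq2 (1766 at an unadjusted p under 0.05).

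Whether the genotype effect differed between diets was tested by interaction. At 4 h 15 genes passed, 5 with a positive and 10 with a negative interaction (edgeR, n = 4 in each of 4 groups; 88 by DESeq2). Cyp4a14 had an interaction of −3.47 ± 0.61, its genotype effect being 6.52 on CD and 3.05 on KD. Slc35f2 (−2.15 ± 0.38) and Nampt (−1.28 ± 0.21) were also negative, and Axin2 (1.79 ± 0.32) and Rab36 (1.75 ± 0.30) positive, each with an adjusted p of 0.0125. The count ran from 7 without WT KD 4 h replicate 4 to 29 without WT KD 4 h replicate 2. It was 24 without WT KD 4 h replicate 1, 27 without KO KD 4 h replicate 4, 25 without KO CD 4 h replicate 3 or KO KD 4 h replicate 3, 8 without KO CD 4 h replicate 2, and 9 without WT CD 4 h replicate 1, 2 or 3, WT KD 4 h replicate 3 or KO KD 4 h replicate 2. At 24 h 0 genes passed in edgeR, against 1221 at an unadjusted p under 0.05 and 57 by DESeq2. The edgeR count was 11 and 16 without WT CD 24 h replicates 1 and 4, 13 without KO CD 24 h replicate 2, 7 without KO KD 24 h replicate 3, and 2 without WT KD 24 h replicate 1 or KO KD 24 h replicate 2. It rose furthest without the 4 libraries holding muscle transcripts, as given in the part on processing.

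Whether the genotype effect differed between fasting times was tested within each diet. On CD 88 genes passed, 17 positive and 71 negative (edgeR; 194 by DESeq2). Cyp4a14 (−6.42 ± 0.64, adjusted p = 1.06e-06) and Ehhadh (−3.39 ± 0.50, adjusted p = 0.00104) had negative interactions. Ehhadh averaged 1140 CPM in KO and 223 CPM in WT at 4 h, and 1230 and 2520 CPM at 24 h. Slc35f2 (−2.57 ± 0.38) was negative as well and Limd2 (1.17 ± 0.21) positive. The count was 44 without WT CD 4 h replicate 3, 52 and 55 without KO CD 4 h replicates 1 and 2, 57 without KO CD 24 h replicate 3 and 810 without the 4 libraries holding muscle transcripts. The 810 rests on replicates 3 and 4 alone in KO CD 24 h. On KD 37 genes passed, 22 positive and 15 negative (edgeR; 179 by DESeq2), including P2ry1 (1.86 ± 0.29) and Dsg1c (3.44 ± 0.55) upward and the bile salt pump Abcb11 (−1.67 ± 0.29) downward. Dsg1c averaged 14.8 ± 3.78 CPM in WT KD 4 h livers and 1.55 ± 0.593 in KO KD 4 h livers, against 2.75 ± 1.2 and 3.07 ± 1 at 24 h. That count was 150, 11, 22 and 10 without WT KD 24 h replicates 1 to 4, 15 without WT KD 4 h replicate 4, 8, 10 and 136 without KO KD 4 h replicates 1, 2 and 3, and 15, 11, 23 and 60 without KO KD 24 h replicates 1 to 4.

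Whether the diet effect differed between fasting times was tested within each genotype. In WT livers 1856 genes passed, 1097 positive and 759 negative (edgeR, n = 4 in each of 4 groups). Hn1l (2.01 ± 0.20), the cysteinyl-tRNA synthetase Cars (1.96 ± 0.22) and Pde9a (1.82 ± 0.20) were positive, and Osbpl3 (−5.77 ± 0.58), P2ry1 (−2.76 ± 0.30) and Nampt (−1.98 ± 0.21) negative. In KO livers 201 genes passed, 114 positive and 87 negative (edgeR; 447 by DESeq2), with the cholesterol synthesis genes Fdps (5.62 ± 0.84) and Cyp51 (4.88 ± 0.76) positive and Cyp7a1 (−4.34 ± 0.84) negative. The KO count was 78, 96, 130 and 100 without KO CD 4 h replicates 1 to 4, 383, 131 and 122 without KO CD 24 h replicates 1, 2 and 4, 51 without KO KD 4 h replicate 4, and 109, 91, 91 and 110 without KO KD 24 h replicates 1 to 4. It also rose without the 4 libraries holding muscle transcripts and fell without the 4 that stood apart, as given in the part on processing. The interaction of all 3 factors passed for 18 genes, 15 positive and 3 negative (edgeR; 74 by DESeq2). Osbpl3 (4.64), Krt23 (4.60) and Tmtc2 (2.04) led it, all with an adjusted p of 0.0064, and without the 3 libraries low in Yam1 they were at 4.56, 4.48 and 2.02 with an edgeR adjusted p of 0.0843. That count was 4 without WT CD 24 h replicate 2, WT KD 24 h replicate 2, KO CD 24 h replicate 3, KO KD 4 h replicate 2 or KO KD 24 h replicate 4, and 5 without KO CD 4 h replicate 1 or 3 or KO KD 24 h replicate 1. It was 6 without WT CD 4 h replicate 4, WT KD 4 h replicate 4, WT KD 24 h replicate 3 or KO CD 4 h replicate 2, and 8 without WT CD 4 h replicate 3. It was 31 without KO CD 24 h replicate 2, 32 and 37 without WT CD 24 h replicates 3 and 4, and 42 without KO CD 4 h replicate 4.

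The genotype effect was also set beside the effects of diet and fasting across 14438 genes, using contrasts that share no library. The effect of genotype on CD at 4 h had a Pearson correlation of −0.211 (Spearman −0.229) with the diet effect in WT livers at 24 h, and of −0.083 (Spearman −0.076) with the fasting effect in WT livers on KD. For the effect of genotype on KD at 24 h the values were 0.177 (Spearman 0.23) with the diet effect in WT livers at 4 h and 0.195 (Spearman 0.214) with the fasting effect in WT livers on CD. Over the 9511 genes of at least 5 CPM these last were 0.308 (Spearman 0.38) and 0.253 (Spearman 0.326). Of the 264 genes called on CD at 4 h, 68 had the same sign in the diet contrast beside it and 129 in the fasting contrast. Of the 571 called on KD at 24 h, 370 and 380 had the same sign.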

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

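The tests of explanations and of other splits in this part were chosen only after the results were seen, whereas the interaction tests belonged to the design. Single libraries were set against the rest of their group with Dixon's test. It singled out 16 of 104 groups of values, where independent, normally distributed values give about 1 in 20, or 5.2. The measures are related to each other. Some, such as Acta1, Yam1 and the diet position, are those by which libraries already stood apart. The 5.2 is therefore no expectation for these values.

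The libraries labelled KO CD 24 h replicate 4 and KO KD 24 h replicate 4 lay near the other diet, at positions of 0.98 and 0.44, where the other 3 libraries of each group lay at 0.29 to 0.47 and 0.96 to 1.01. Scd1, which passed for diet in WT livers at both times and so enters the positions, was at 130 and 3770 CPM. Equal mixing of both RNAs is argued against by the difference of 0.54 between their positions, beyond the largest range of the other 3 (0.18). Exchanged diet labels may account for the positions, and passed a first test on positions alone. In a condition added after that, the mean of the cholesterol synthesis genes was 4.29 log2 CPM in the library labelled KD. That lay within the other CD libraries (4.27 to 4.58), as an exchange needs. The library labelled CD was at 3.92, below both these and the other KD libraries (5.14 to 6.44). It was nearer the CD libraries, which goes with its own label. Cyp17a1, at 143 CPM in the library labelled KD and 13.4 CPM in that labelled CD, was nearer the other diet in both. An exchange and a difference between animals therefore cannot be told apart. No biological explanation was tested, and both libraries were kept under their labels.

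Skeletal muscle transcripts were present in WT CD 24 h replicate 1, KO CD 24 h replicates 1 and 2 and KO KD 4 h replicate 4. Induction by the longer fast in KO livers on CD is argued against by another library of that group with Acta1 at 0.0622 CPM and by the 4 h library at 162 CPM. Muscle tissue carried along at dissection may account for them: of 15 further muscle markers with a median under 1 CPM in the other 28 libraries and at least 1 CPM in some library, 100% were above all 28 in all 4, with Mb at 33 to 101 CPM and Myh1 at 41.2 to 186 CPM. That criterion was set after the result of an earlier one, at least 10 times the median of the other 28, which 14 of 19 markers (73.7%) met and which left the question undecided, and its bound of 1 CPM in some library leaves out Tnnc2, near 0 in all 4. Neb and Eno3, which failed the earlier criterion as did Tpm2, Casq1 and Tnnc2, had medians of 20.7 and 5.67 CPM in the other 28 livers, and a biological source within the liver stays open as untested.

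Genes near Slc27a2 on chromosome 2 were called between the genotypes in 3 or 4 of the 4 conditions more often than elsewhere. Within 10 Mb of Slc27a2 the share was 4.04% (8 of 198 genes), against 0.53% (5 of 944) elsewhere on the chromosome (Fisher's exact test, p = 0.000418) and 0.602% (80 of 13295) on other chromosomes. Within 1 Mb it was 3.7% (1 of 27; Fisher's exact test against elsewhere on the chromosome, p = 0.156). These p values take genes as independent, which neighbours are not. An effect on the genes beside Slc27a2 alone is argued against by the share from 1 to 10 Mb away, 4.09% (7 of 171; Fisher's exact test, p = 0.000713). Alleles of another strain carried along with the disrupted gene stay open as a hypothesis, which read sequences could test and counts cannot. The 8 genes are Bmf, Disp2, Exd1, Chp1, Catsper2, Eif3j1, Hdc and Gm14022, from 118528757 to 129065686 on chromosome 2, all of them found through their calls. The count of Eif3j1 is uncertain, since it shares reads with Eif3j2.

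Other single libraries stood out as follows. KO CD 4 h replicate 4 had 121 CPM of Slc27a2 against 198 to 207 in its group. Yam1 took 0.058% of counts in WT CD 4 h replicate 4 (others 3.78 to 4.45%) and 1.71% in KO KD 24 h replicate 4 (others 3.86 to 4.03%). Acta1 was at 86.1 CPM in WT CD 24 h replicate 1, 0.46 CPM in WT KD 4 h replicate 1, 0.0407 CPM in KO CD 4 h replicate 3 (under its floor of 0.121 CPM, with 0 in the others, so that the test decides nothing there) and 162 CPM in KO KD 4 h replicate 4. Cyp4a14 was at 10200 CPM in KO KD 24 h replicate 4 (others 6010 to 6290). In mean log2 CPM of a list, KO KD 4 h replicate 1 was at 6.11 for lipogenesis (others 5.85 to 5.87), and KO CD 24 h replicate 4 at 6.53 for the acute phase (others 7.32 to 7.35). WT KD 4 h replicate 2 was at 5.89 (others 4.46 to 4.53) and WT KD 24 h replicate 4 at 6.63 (others 5.75 to 5.87) for cholesterol synthesis. KO KD 24 h replicate 3 was at 4.33 for macrophage markers (others 3.56 to 3.62), and WT CD 24 h replicate 1 at 5.68 (others 8.65 to 8.97) and KO KD 4 h replicate 3 at 9.02 (others 8.64 to 8.65) for male-biased genes.

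Effects that differed between groups by the interaction test were also singled out. Genotype by diet at 4 h gave 15 genes, with Rab36 at 1.75, Axin2 at 1.79, Sgk2 at 1.28, Nampt at −1.28, Cyp4a14 at −3.47 and Slc35f2 at −2.15. Genotype by fasting gave 88 genes on CD, with Limd2 at 1.17, Pcnxl4 at 0.97, Akap17b at 1.33, Cyp4a14 at −6.42, Ehhadh at −3.39 and Slc35f2 at −2.57. On KD it gave 37 genes, with P2ry1 at 1.86, Dsg1c at 3.44, Abcb11 at −1.67, Mad2l2 at −0.97 and Tubb4b at −1.32. Diet by fasting gave 1856 genes in WT, with Hn1l at 2.01, Cars at 1.96, Pde9a at 1.82, Osbpl3 at −5.77, P2ry1 at −2.76 and Nampt at −1.98. In KO it gave 201 genes, with Fdps at 5.62, Cyp51 at 4.88, Ttn at −13.69, Cyp7a1 at −4.34 and Ddx19b at −0.73. The interaction of all 3 factors gave 18 genes, with Tmtc2 at 2.04, Krt23 at 4.60, Osbpl3 at 4.64, Hn1l at −1.47 and Atp8b1 at −1.31. Ttn, a muscle gene, was at −2.29 without the 4 libraries holding muscle transcripts and −7.57 without KO KD 4 h replicate 4, and no longer passed in either case. Calls lost with a single library left out were those of Sgk2 (9 libraries, 1.15 to 1.30), Pcnxl4 (0.92 without WT CD 4 h replicate 4 and 0.91 without KO CD 24 h replicate 4), Akap17b (1.21 without WT CD 4 h replicate 3 and 1.15 without KO CD 24 h replicate 4) and Mad2l2 (−0.89 and −0.94 without KO KD 4 h replicates 1 and 2). Single libraries also ended the calls of Tubb4b (WT KD 24 h replicate 2 or 4, KO KD 4 h replicate 1 or 2, KO KD 24 h replicate 2; −1.31 to −1.22) and, in the interaction of all 3 factors, of Hn1l (11 libraries) and Atp8b1 (18 libraries).

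Other splits of the same libraries into groups of equal size were refitted with only the groups of each contrast. For KO against WT, 1 of 35 splits, the real one, gave as many genes in each condition. That is the smallest share 35 splits can reach, and it was read for every pairwise contrast without correction. Chance is therefore not taken as excluded for any single contrast. The other splits also mix the compared groups, so a real effect widens their spread. Their counts are therefore no measure of the number expected by chance. The real counts and the highest of the other splits were 552 and 2 on CD at 4 h, 275 and 6 on KD at 4 h, 13 and 1 on CD at 24 h, and 437 and 1 on KD at 24 h. The same held for the longer fast, with 1552 and 0 in WT on CD, 967 and 1 in WT on KD, 2368 and 3 in KO on CD and 1403 and 2 in KO on KD, and for diet at 4 h, with 5228 and 0 in WT and 1127 and 1 in KO. Chance cannot be excluded either for diet in WT at 24 h, where 2 of 35 splits reached the real count of 46. There a split that exchanged WT CD 24 h replicates 1 and 2 with WT KD 24 h replicates 2 and 3 gave 746. For diet in KO at 24 h the test decides nothing, since all 35 splits reach a real count of 0 (edgeR) whatever the data, and the split that exchanged the libraries labelled replicate 4 gave 99. The split that gave 746 set WT CD 24 h replicates 1 and 2 and WT KD 24 h replicates 1 and 4 against the rest. The numbers in their sample titles neighbour each other, and those of the other libraries lie below or above them. A block tied to these numbers was not tested. The exchange that gave 99 was examined above and left undecided.

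For the interactions 100 splits were drawn, the real one included. An earlier run with fewer draws had seemed to exclude chance for diet by fasting in KO, and the number was raised after that result was seen. Each draw shuffled genotype, or diet for diet by fasting, among libraries alike in the other factors. This also scatters the effect of the shuffled factor itself. The draws therefore test against no effect of that factor rather than against no interaction, and none of them can exclude chance for an interaction. The real split alone reached its count for genotype by diet at 4 h (real 47, highest other 14) and diet by fasting in WT (real 1272, highest other 787). For genotype by fasting on CD (2 splits; real 29, highest other 406) and on KD (3 splits; real 65, highest other 153) and the interaction of all 3 factors (2 splits; real 18, highest other 19) the share was under 5%, but other splits gave higher counts and 100 draws fix so small a share poorly, so chance is not taken as excluded. It cannot be excluded for diet by fasting in KO (5 splits; real 117, highest other 1702). For genotype by diet at 24 h the test decides nothing, since all 100 splits reach a real count of 0 (edgeR), and the highest other count of 9 depended on the draw, being far higher in the earlier run. A draw that leaves the labels intact in some groups and scatters them in others can call many genes through the shuffled factor's own effect. The high counts therefore do not show a structure of the samples.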

How the results depend on the processing

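The settings that left out 2, 3 or 4 libraries were chosen after seeing the data, and the cause of each change below was not tested unless stated. No paired analysis was possible because replicate numbers follow the order of deposit only. Alternatives for FPKM values (pseudocount, filter) were not run because counts were given, and the fit of only the groups in a contrast has no form for the interaction of all 3 factors. Of 872 calls of named genes, 513 were kept under every alternative. RLE size factors kept 858 and weakened 14, no filter kept 819 and weakened 53, and DESeq2 kept 869 of 870. A fit of only the groups in a contrast kept 702 of 854, and its smaller sample lowers the residual degrees of freedom. The settings without 2, 4 apart, 4 muscle and 3 low Yam1 libraries kept 791, 768, 794 and 733, and single libraries left out kept 6141 of 7336. Depth limits genes near the floor of 3 counts, such as Cidea in WT livers.

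Fasting in WT livers on CD reversed for Cyp2a4 (−0.46, −0.46 and −0.45) and Gsta1 (−1.38, −1.38 and −1.37) without the 4 libraries apart, without the 4 muscle libraries and without WT CD 24 h replicate 1. With 1 library left out, Cyp2a4 ranged from −0.45 to 4.04 and Gsta1 from −1.37 to 4.19. Des reversed to −0.07 for fasting in KO livers on CD without the 4 muscle libraries.

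Counts of genes moved over 1.5-fold as follows. With DESeq2 the count was 651 for KO against WT on KD at 4 h, 563 on CD at 24 h and 892 on KD at 24 h, 700 for diet in WT at 24 h and 113 in KO at 24 h. For interactions it was 88 (genotype by diet, 4 h), 57 (24 h), 194 (genotype by fasting, CD), 179 (KD), 447 (diet by fasting, KO) and 74 (all 3 factors). RLE gave 3 for genotype by diet at 24 h. Without the filter, which adds genes to the tests, there were 373 for KO against WT on KD at 24 h, 3 for diet in KO at 24 h, 4 for genotype by diet at 24 h and 31 for all 3 factors.

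With only the groups in the contrast the counts were 552 for KO against WT on CD at 4 h and 13 at 24 h, 46 and 0 for diet at 24 h in WT and KO, 1552 and 967 for fasting in WT on CD and KD, 47 for genotype by diet at 4 h, 29 and 65 for genotype by fasting on CD and KD, and 117 for diet by fasting in KO. The 0 is of edgeR, beside 1766 genes at an unadjusted p under 0.05 in the full fit and 113 by DESeq2.

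Without the 2 libraries near the other diet there were 115 for KO against WT on CD at 24 h and 374 on KD at 24 h, 52 for diet in KO at 24 h, 805 for fasting in KO on KD, 63 for genotype by fasting on KD, 96 for diet by fasting in KO and 8 for all 3 factors. Without the 4 libraries apart there were 694 for KO against WT on KD at 4 h and 197 on CD at 24 h, 166 for diet in KO at 24 h, 836 for fasting in KO on KD, 67 and 1 for genotype by diet at 4 and 24 h, 136 for genotype by fasting on KD, 61 for diet by fasting in KO and 7 for all 3 factors.

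Without the 4 muscle libraries there were 863, 2247 and 960 for KO against WT on KD at 4 h, CD at 24 h and KD at 24 h, 4259 for fasting in KO on CD, 66 and 248 for genotype by diet at 4 and 24 h, 810 and 247 for genotype by fasting on CD and KD, and 578 for diet by fasting in KO. Those counts that involve KO CD 24 h rest on its replicates 3 and 4 alone, the latter near the other diet. Without the 3 libraries low in Yam1 there were 227 for KO against WT on KD at 24 h, 191 for diet in WT at 24 h, 47 and 9 for genotype by fasting on CD and KD, and 0 for all 3 factors (edgeR, against 18 with all libraries). Of 124 calls of gene lists, 1 held with an estimated correlation.

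With 1 library left out, KO against WT ranged from 166 to 239 on CD at 4 h, 210 to 435 on KD at 4 h, 105 to 509 on CD at 24 h and 226 to 939 on KD at 24 h. Diet ranged from 2541 to 3928 in WT at 4 h, 187 to 610 in WT at 24 h, 463 to 1881 in KO at 4 h and 0 to 26 in KO at 24 h. Fasting ranged from 1831 to 3165 in WT on CD, 1002 to 1862 in WT on KD, 1536 to 3434 in KO on CD and 747 to 1673 in KO on KD. Interactions ranged from 7 to 29 and 0 to 16 for genotype by diet at 4 and 24 h, 44 to 124 and 8 to 150 for genotype by fasting on CD and KD, 1349 to 2344 and 51 to 383 for diet by fasting in WT and KO, and 4 to 42 for all 3 factors. Libraries that moved a count over 1.5-fold are named in the report.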

Other observations

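The test of resemblance to fasting in this part was written before its result was seen, and the test of Eif3j1 and Eif3j2 was chosen after it. Single genes of autophagy and the lysosome changed with diet and fasting. The mitophagy receptor Bnip3 averaged 135 ± 11.6 CPM in WT livers on CD at 4 h, 439 ± 10.1 on KD at 4 h and 464 ± 186 on CD at 24 h, with log2 fold changes of 1.70 for diet (edgeR adjusted p = 6.53e-06, n = 4 each) and 1.78 for fasting (edgeR adjusted p = 3.7e-06). The lysosomal protease Ctsl and lipase Lipa had log2 fold changes of −1.20 and −1.41 on KD at 4 h in WT livers. Ctsl was higher after the longer fast on KD by 1.31 in WT and 1.28 in KO livers (edgeR adjusted p = 5.92e-05 and 0.000216). Of 17 genes of the list, 8 were lower and 2 higher on KD in WT livers at 4 h (adjusted p = 0.8 with an estimated correlation).

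Of 16 antioxidant targets of NRF2, 6 were lower and 2 higher on KD in WT livers at 4 h (6 and 3 over the list alone; adjusted p = 0.768 with an estimated correlation). Gstm2, a glutathione transferase, was lower on KD at 4 h in WT (−1.72) and KO livers (−1.65), at 15.6 and 11.4 CPM against 51.6 and 35.9 CPM on CD. Glutathione reductase (Gsr) was higher in KO than in WT livers on KD at 4 h by 0.57 (edgeR adjusted p = 0.00315). The female-biased monooxygenase Fmo2 was higher after the longer fast on CD by 3.11 in WT and 2.2 in KO livers, with means of 40.7 and 37.7 CPM at 24 h. In the male WT CD 24 h replicate 1, Cyp2a4 was at 7.45 CPM and Gsta1 at 23.5 CPM, against at most 0.34 and 0.37 CPM in the rest of its group. That library had the Y-linked gene Ddx3y at 137.5 CPM and Xist at 0.79 CPM.

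Eif3j2 was higher in KO livers in every condition, and reads of its near-identical copy Eif3j1 may account for this. In WT livers on CD at 4 h Eif3j1 and Eif3j2 were at 53.2 and 1.07 CPM, and in KO livers at 34.6 and 17.6 CPM. Their sum was 54.3 ± 3.19 CPM in WT and 52.2 ± 3.96 CPM in KO, and over the 4 conditions the mean log2 ratio of the sums was −0.09, so the hypothesis that reads moved between the copies stays open. Eif3j1 is also among the genes near Slc27a2, and a real rise of Eif3j2 with a fall of Eif3j1 was not tested.

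The hypothesis that the genotype effect on CD at 4 h resembles the effect of fasting was tested across genes against the longer fast in WT livers on KD, which shares no library with it. The correlation was −0.083, which argues against it for that comparison alone. The PPARα targets had medians of 1.39 for genotype on CD at 4 h and 1.72 for fasting in WT livers on CD, which share libraries. For genotype on KD at 24 h and fasting in WT livers on CD, which share none, the correlation was 0.195 (0.253 over genes of at least 5 CPM), so a resemblance in other conditions stays open.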
